A study of Zea mays with 4 samples.

How the data were processed

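Whole B73 maize seedlings were profiled by RNA-seq in 4 libraries, 2 from control plants and 2 from plants kept at 4 °C for 24 h. The deposited values are raw counts of fragments per gene in one table, with a column per library and no pooling, per the file headers. The authors counted with featureCounts 1.6.4 against the B73 RefGen_v4 annotation, release 43, per the file headers, summing over gene identifiers. The command in the header counts read pairs as fragments, does not use strand, and does not set the options for reads that map to several places or overlap several genes. Such reads are therefore left out of the counts. fastp and HISAT2 are named in the submitters' processing notes, and their versions are not given in the sources used here. The names of the alignments in the header contain the word filter, and what was filtered is not given in the sources used here. The name for cold replicate 1 alone also contains the word sample, and its meaning is not given. Whether RNA was selected by poly(A) tail or depleted of ribosomal RNA is not given there either. The table also holds the exon length of each gene, other values deposited by the authors, which were checked against the exon coordinates in the same rows.

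The table lists 46430 loci, with totals of 28493929, 23713326, 24176378 and 20942576 fragments in control replicates 1 and 2 and cold replicates 1 and 2. Between 26984 and 27667 genes had a fragment in each library. The replicates were compared by a chi-square test of their counts over genes with at least 20 fragments. The statistic per degree of freedom was 11.3 in control and 25.0 in cold, so neither pair looks like repeat deposits of 1 library.

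Identifiers were linked to names through a RefSeq gene table of the assembly Zm-B73-REFERENCE-NAM-5.0. That is another build, so it was used for names only and coordinates are those of the deposited table. All 365 organelle identifiers with a locus tag matched, and 0 of 44146 nuclear gene identifiers did. Of 31 gene lists fixed before the data were examined, 30 need names of nuclear genes and were not tested. Name patterns of the lists for nuclear photosystem and ribosomal protein genes also hit organelle genes, which were counted only under the organelle list. The organelle list was tested, and 6 further sets were added after seeing the data: mitochondrial genes, plastid genes, nuclear short non-coding RNA loci, single-exon genes, genes with over 10 exons, and genes on unplaced contigs.

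Genes were kept by edgeR's filterByExpr (minimum count 10, minimum total 15), which left 23169 genes and removed 23261. Libraries were scaled by TMM factors of 1.053, 1.100, 0.9664 and 0.8935. Differences were tested with the quasi-likelihood F test of edgeR 4.0.16 in R 4.3.3, two-sided, with condition as the only term, and p-values were adjusted by Benjamini-Hochberg with a threshold of 0.05. The common biological coefficient of variation was 0.143 and the prior degrees of freedom 5.54. The standard error of a log2 fold change is its size divided by the square root of F. CPM values use the TMM-scaled library sizes and are given as mean ± SD. Gene lists were tested with camera (limma 3.58.1) at a preset correlation of 0.01, and with fry. fry asks whether a list moves on balance one way, and gave p = 0.007 for all organelle genes, 0.000353 for mitochondrial genes and 0.0633 for plastid genes. Counting intervals are 95% intervals of the ratio of summed fragments.

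Named genes were chosen by a rule written before the data were examined: those with the largest changes in each direction among called genes with a mean of at least 10 CPM and a known name, up to 3 such members of each gene list, and, where identifiers lack names, the 2 identifiers with the largest change in each direction. Other genes and regions in the text were chosen after their values were seen. Neighbouring genes were compared over tested nuclear genes on chromosomes 1 to 10, using ranks of the log2 fold changes over all these genes, against 1000 permutations of the values within chromosomes.

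The alternatives were RLE, upper-quartile and no scaling factors, removal of the 20 most abundant genes, DESeq2 1.42.0, no low-count filter or a stricter one (5 CPM in 2 libraries), the replicate number as a block, stricter thresholds, and leaving out each library in turn. Where 1 library is left in a condition, it is assumed to vary like the others. The test was run on simulated data drawn from the means and library sizes of these 4 libraries over 23169 genes. It recovered 81% of 100 genes changed 2-fold and 100% of 100 genes changed 4-fold, with 9 false calls among 190. The changed genes were not drawn from genes with low mean counts, and the simulated spread followed the trend over abundance alone. Far fewer genes were changed than were called in the real data. These rates therefore do not cover genes with few fragments or the share of false calls in the real comparison. Nucleosome and histone-mark assays named in the series were not analysed here.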

Results

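RNA-seq was carried out on whole seedlings of the maize inbred line B73, the line whose genome serves as the maize reference. Plants grew in soil for 9 days at 25 to 28 °C with 16 h of light and 8 h of dark. They were then divided between continued growth at that temperature (control) and 24 h at 4 °C (cold), and material from 10 plants aged 10 days was collected. The series sets cold against control within a study of how nucleosome stability responds to cold in maize. The question addressed here is which transcripts differed in abundance after a day of chilling. Each condition had 2 libraries, with 28493929 and 23713326 fragments assigned to genes in the control libraries and 24176378 and 20942576 in the cold ones. A floor of 3 fragments in a library corresponded to between 0.105 and 0.143 CPM by library totals without TMM factors. CPM is the number of fragments scaled to a common library size. On the log scale the control libraries correlated across genes at r = 0.987 and the cold libraries at r = 0.982, and pairs from different conditions at 0.871 to 0.884. Genes are not independent replicates, so these values describe the libraries only. The labels do not say whether the libraries of a condition came from separate growth batches, so p-values measure only the spread between these samples, which may be technical. The alignments of both control libraries carry a common number in their names and those of the cold libraries other numbers, and what the number stands for is not given in the sources used here.

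A large part of the seedling's genes differed in transcript abundance after cold, in similar numbers in each direction. Of 23169 genes tested, 6256 were higher in cold and 6259 were lower (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p under 0.05), which is 27.0% each way. Changes of at least 2-fold were found for 3487 higher and 3395 lower genes. The largest changes were mostly increases: 267 genes rose over 16-fold and 90 fell that far, although the fitted fold of genes with almost no fragments in a condition depends on the model's prior count. Genes called higher took 21.3% and 21.8% of the fragments of the control libraries and 43.0% and 43.7% of the cold libraries. Genes called lower took 27.1% and 26.9% in control and 12.5% and 11.8% in cold. Mitochondrial transcripts, counted as a sign of RNA quality, also took more of the cold libraries, 0.134% and 0.112% of fragments against 0.0767% and 0.0703%. The balance of directions depended on how libraries were scaled. With library totals alone 4768 genes were higher and 8188 lower (36.8% of calls higher), and with upper-quartile factors 5199 were higher and 7849 lower (39.8%). Without control replicate 2, 4117 genes were called lower, and without cold replicate 1, 176 genes fell over 16-fold.

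**Figure D1:**
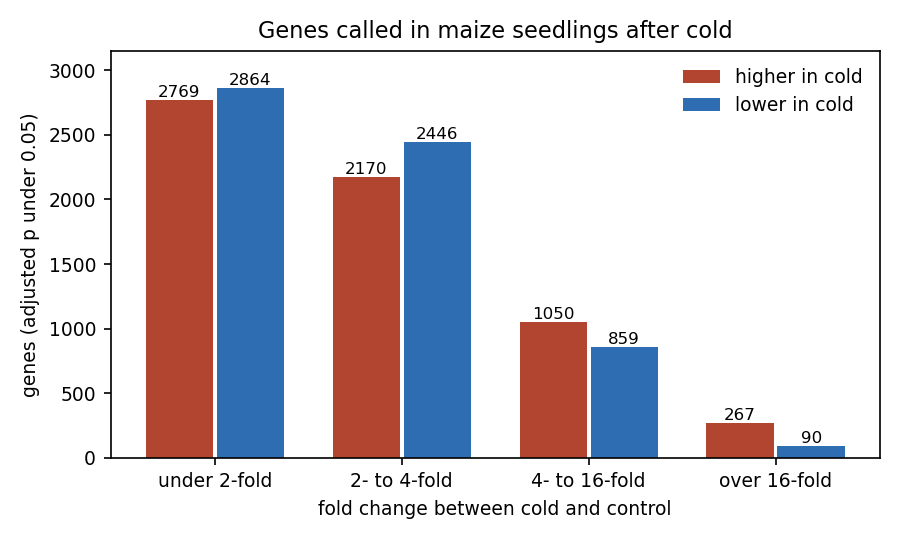
Number of genes called higher (red) or lower (blue) in cold seedlings against control, grouped by the size of the fitted fold change on the x axis. Bars start at 0 and the numbers above them are gene counts. The directions are nearly even up to 4-fold, with 2769 and 2864 genes under 2-fold, while 267 genes rose and 90 fell over 16-fold.

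Some genes went from near silence to clear expression. There were 40 genes with a control mean under 0.1 CPM that reached at least 1 CPM in both cold libraries, and all 40 were called higher. Of these, 9 had no fragment in either control library. Their median cold level was 3.54 CPM and the highest was 42.1 CPM. In the other direction, 24 genes with a cold mean under 0.1 CPM had at least 1 CPM in both control libraries. All 24 were called lower, 3 of them had no cold fragment, and their control levels had a median of 1.55 CPM and reached 2.97 CPM. These classes were set after the data were seen, and all their CPM values use library totals without TMM factors.

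The nuclear genes carry only locus identifiers here, so the steepest changes at a mean of at least 10 CPM are given by identifier and position in B73 RefGen_v4. Zm00001d000020, a single-exon gene on the minus strand of the unplaced contig B73V4_ctg150 (1370542 to 1371450), had no fragment in the control libraries and 500 and 869 in the cold ones. Its cold level was 33.9 ± 17.7 CPM (SD, n = 2, adjusted p = 0.00011). The summed cold fragments, scaled by library size, were 608 times a floor of 3 fragments over the control group. The 95% counting interval of the cold to control ratio began at 494. Zm00001d014970, with 3 exons on the minus strand of chromosome 5 (70576573 to 70577620), had 0 and 1 control fragments and 830 and 1043 cold fragments. The ratio was 2497, with a 95% counting interval of 448 to 98663, and the log2 fold change was 10.96 (SE 0.50, adjusted p = 1.7e-05). With a library left out it lay between 10.04 without control replicate 1 and 13.10 without control replicate 2, which leaves no control fragment. Zm00001d048660, with 2 exons on the plus strand of chromosome 4 (2847383 to 2847973), fell from 21.9 ± 11.2 to 0.128 ± 0.182 CPM (n = 2 each, log2 fold change -7.22, SE 0.67, adjusted p = 0.00015). It had 894 and 365 control fragments and 6 and 0 cold fragments, a control to cold ratio of 157 with a 95% counting interval of 72.1 to 430. The fitted log2 fold change was -12.10 without cold replicate 1, which leaves no cold fragment, -6.38 without cold replicate 2 and -6.56 without control replicate 1. Zm00001d046728, a single-exon gene on the plus strand of chromosome 9 (103756845 to 103757420), fell from 46.2 ± 17.0 to 0.760 ± 0.318 CPM (n = 2 each, log2 fold change -5.88, SE 0.37, adjusted p = 3.7e-05). Fragments without molecular identifiers are not independent molecules, so intervals and floors cover counting error only. Reads from near-identical gene copies were left out of the counts where they mapped to several places, and reads from an overlapping antisense transcript cannot be told apart from the gene's own because strand was not used.

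The largest shifts in transcript mass came from other loci, picked by their change in CPM after the values were seen. A gene with 3 exons on the minus strand of chromosome 6 (22131705 to 22136034) rose from 261 ± 34.5 to 7272 ± 2019 CPM (SD, n = 2 each). That is from 0.0261% to 0.727% of the TMM-scaled library size, a 27.9-fold increase (adjusted p = 3.8e-05). A gene with 9 exons on the plus strand of chromosome 1 (25632515 to 25636718) rose 316-fold, from 17.9 ± 3.39 to 5649 ± 1439 CPM (adjusted p = 1.4e-05). A gene with 7 exons on the plus strand of chromosome 3 (31827897 to 31838331) fell 12.3-fold, from 2764 ± 50.2 to 224.6 ± 12.9 CPM (adjusted p = 2.2e-05). Further along chromosome 3, a gene with 3 exons on the plus strand (139135030 to 139136095) went from 3063 ± 795 to 1219 ± 64.6 CPM, with a log2 fold change of -1.33 (SE 0.23, adjusted p = 0.0025). Among the 100 most abundant nuclear genes, 20 were higher, 18 were lower and 62 were not called.

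Chromosomes 1 to 10 did not stand apart from each other. Between 25.3% and 28.0% of the tested genes of a chromosome were higher in cold and between 26.2% and 28.6% were lower (chi-square test over the 10 chromosomes and 3 outcomes, p = 0.945). Of 120 tested short non-coding RNA loci in the nuclear genome, 25 were higher and 19 lower, with a median log2 fold change of 0.36. As a set they did not differ from the other genes (camera adjusted p = 0.63). With DESeq2, 15 of these loci were higher and 9 lower, and without control replicate 2 or cold replicate 1 the lower count was 9 or 11. The 154 annotated microRNA loci had 0 fragments in each of the 4 libraries. Reads that overlap several genes or map to several places were left out, so this does not show that the loci were silent.

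Nuclear genes that lie next to each other changed together more than genes drawn at random, a relation examined after the data were seen. Over 22804 pairs of adjacent tested genes, the rank correlation of the log2 fold changes across genes was 0.072, above the highest of 1000 permutations within chromosomes (0.021). It was strongest in overlapping genes on the same strand (0.631 over 66 pairs), where the gene of origin of a read is least certain. Divergent genes, which start next to each other on opposite strands, had a correlation of 0.278 over 275 pairs with a gap of up to 1 kb and 0.191 over 238 pairs with a gap of 1 to 3 kb. Convergent genes, whose ends face each other, had 0.066 over 928 pairs within 1 kb, and genes on the same strand 0.171 over 621 pairs. Over all distances the values were 0.051 for divergent, 0.058 for convergent and 0.087 for same-strand pairs. For divergent pairs within 1 kb the permutation p was 0.001, the smallest that 1000 permutations can give, and the adjusted p was 0.00165 over 28 relations. For gaps of 1 to 3 kb the adjusted p was 0.0084, and for convergent pairs within 1 kb it was 0.0653. Genes are not independent replicates, and the correlation of the divergent pairs within 1 kb lay between 0.258 and 0.284 with a library left out.

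**Figure D2:**
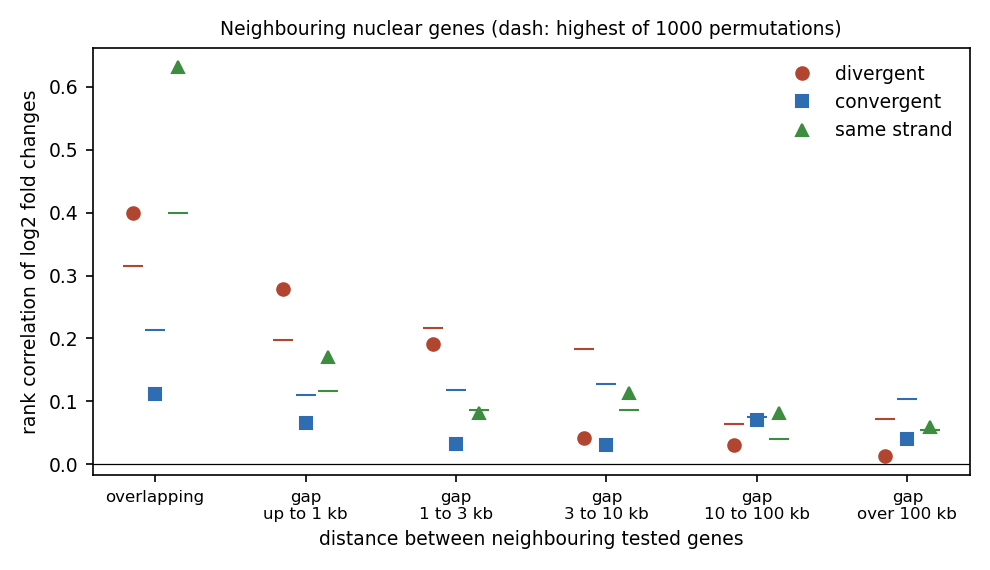
Rank correlation (y axis) of the log2 fold changes of neighbouring tested nuclear genes, by the distance between them (x axis) and their orientation (colour and shape). Dashes mark the highest of 1000 permutations within chromosomes, and divergent pairs within 1 kb lie at 0.278 against 0.066 for convergent pairs.

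Transcripts encoded in the organelle genomes, the only fixed gene list that the identifiers allowed to be tested, were higher in cold as a set. Of 66 tested genes of the mitochondrion and plastid, 24 were higher, 0 were lower and 42 were not called, and adjusted over the list alone 20 were higher and 0 lower. No organelle gene was lower at an unadjusted p under 0.05 in edgeR, and DESeq2 called 17 higher and 0 lower. The median log2 fold change was 0.83 (camera with a preset inter-gene correlation of 0.01, p = 0.0105, adjusted p = 0.0368 over this list and 6 added after the data were seen). With an estimated correlation between genes the call was lost (p = 0.135, adjusted p = 0.473), as it was without cold replicate 1 (median 0.86, p = 0.0539). A stricter filter of 5 CPM in 2 libraries also ended it, with a median of 0.26 over the genes left (p = 0.164 at the preset correlation). Library totals alone moved the median of all genes from -0.03 to -0.24 and left the organelle median at 0.63.

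The rise was found mainly in the mitochondrial genes, a split made after the data were seen. Of 27 tested, 16 were higher and 0 lower (adjusted over the list alone 17 and 0), with a median log2 fold change of 1.18 (camera p = 0.00128, adjusted p = 0.00896; adjusted p = 0.473 with an estimated correlation). DESeq2 called 11 higher and 0 lower, edgeR had 0 lower at an unadjusted p under 0.05, and without control replicate 2 the higher count was 10. Of 8 tested genes for respiratory-chain subunits, ATP synthase subunits and cytochrome c maturation, 7 were higher, with a median log2 fold change of 2.46. The cytochrome c oxidase subunits cox1, cox2 and cox3, part of the terminal complex of the respiratory chain, rose by log2 fold changes of 2.33 (SE 0.28, adjusted p = 0.00048), 2.60 (SE 0.34, adjusted p = 0.00068) and 3.10 (SE 0.41, adjusted p = 0.00072). In CPM (mean ± SD, n = 2), cox1 went from 1.18 ± 0.0668 to 5.93 ± 1.06 and cox3 from 0.633 ± 0.189 to 5.49 ± 2.24. The ATP synthase subunit gene atp6 rose 8.01-fold (adjusted p = 0.0024) and ccmFC, needed for cytochrome c maturation, was also higher (adjusted p = 0.0046). It had 1 fragment in each control library and 13 and 10 in the cold ones, a ratio of 15.3 with a 95% counting interval of 3.79 to 134. The weaker calls of atp4 (0.88, adjusted p = 0.025) and ccmFN (1.90, adjusted p = 0.047) were each lost when a single library was left out, for example at adjusted p = 0.12 and 0.19 without control replicate 1. The log2 fold change of ccmFN rested on the control libraries, at 1.11 without control replicate 1 and 3.56 (adjusted p = 0.010) without control replicate 2. The NADH dehydrogenase subunit gene nad4 had a log2 fold change of 1.16 (SE 0.51) and was not called (adjusted p = 0.091). It was 1.58 (adjusted p = 0.035) without cold replicate 2 and 0.55 (adjusted p = 0.49) without cold replicate 1.

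Ribosomal RNA made up most of the mitochondrial fragments. The large-subunit gene rrn26 (ZeamMr002, mitochondrial genome 400215 to 403766, plus strand) went from 610 ± 57.7 to 1162 ± 84.8 CPM (SD, n = 2 each, log2 fold change 0.93, SE 0.17, adjusted p = 0.0029). Without control replicate 2 its change was 0.84 at an adjusted p of 0.061. The small-subunit gene rrn18 (ZeamMr004, 419620 to 421587, minus strand) rose from 39.3 ± 6.52 to 89.2 ± 9.49 CPM (log2 fold change 1.18, SE 0.15, adjusted p = 0.00064). Of 5 mitochondrial ribosomal protein genes 2 were higher, with log2 fold changes of 2.13 for rps7 (adjusted p = 0.0041) and 1.21 for rps2B (adjusted p = 0.042, lost when any library was left out). A plastid-derived rbcL copy in the mitochondrial genome, rbcL-ct, had a log2 fold change of -0.04 (SE 0.19, adjusted p = 0.86). Of the other mitochondrial genes named with -ct, rrn16-ct (2.28, adjusted p = 0.0042) and orf121-a-ct (1.09, adjusted p = 0.0046) were called higher. The genes orf134-a-ct (1.32), orf146-ct (0.97) and rps7-ct (0.92) were not called. All of them count among the mitochondrial genes tested. Reads that also match copies of organelle DNA in the nuclear genome are absent from these counts where they mapped to several places, so levels of organelle genes are uncertain.

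**Figure D3:**
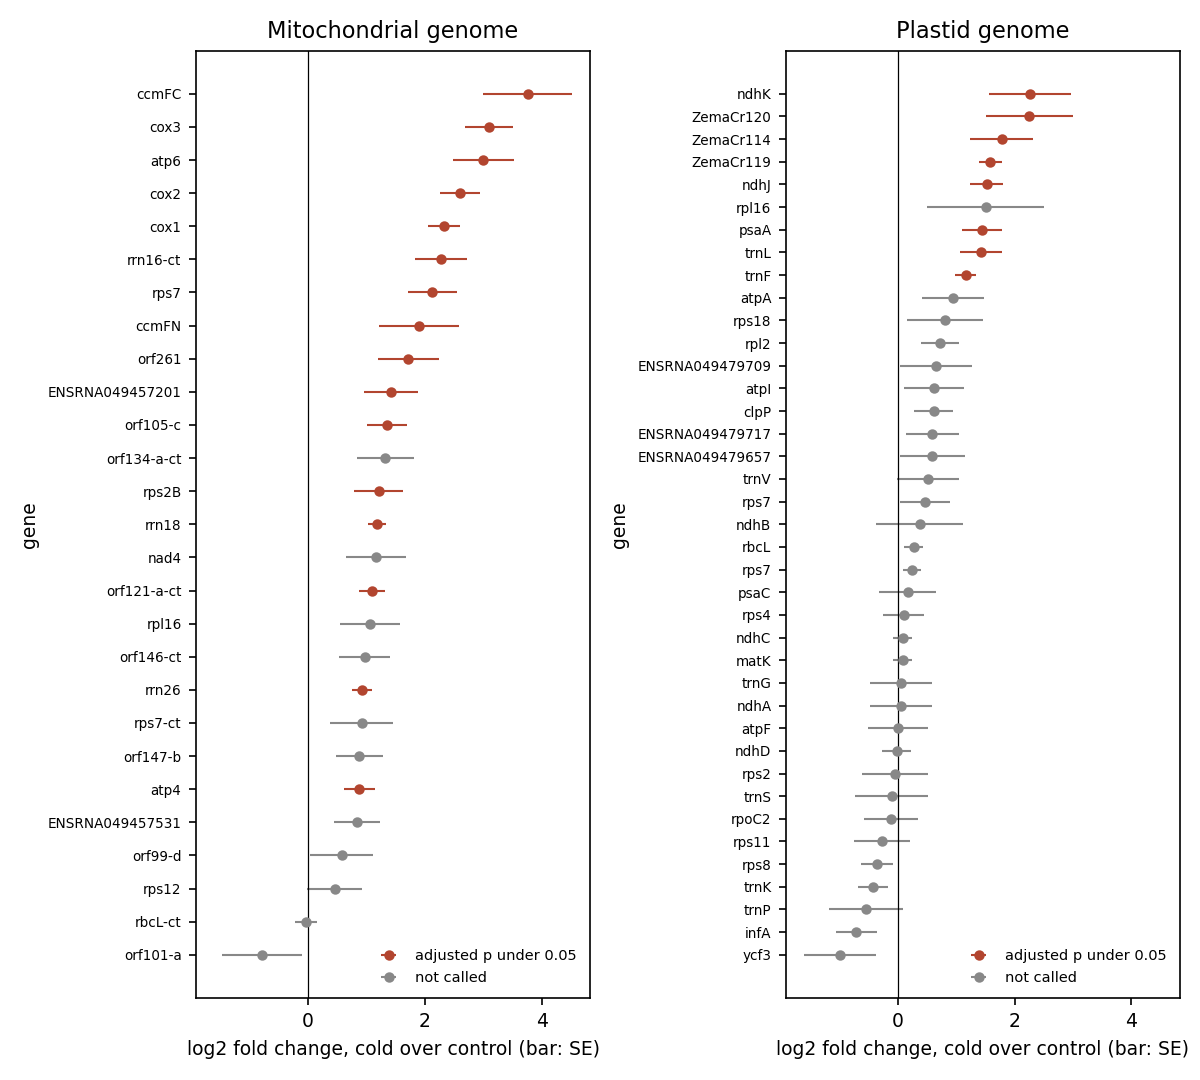
Log2 fold change (x axis, cold over control) of each tested gene of the mitochondrial (left) and plastid (right) genome, with bars of 1 SE; red points were called at an adjusted p under 0.05. Among the mitochondrial genes 16 of 27 were called higher, and among the plastid genes 8 of 39.

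Among plastid genes 8 of 39 were higher and 0 lower (adjusted over the list alone 5 and 0), with a median log2 fold change of 0.37. As a set the plastid genes were not called against the other genes (camera adjusted p = 0.63). DESeq2 called 6 higher and 0 lower, and edgeR had 0 lower at an unadjusted p under 0.05. Without control replicate 2 there were 4 higher, and without control replicate 1 or cold replicate 2 there was 1 lower, as with library totals alone, and with no low-count filter there were 2. The tRNA gene trnF (ZemaCt138, plastid genome 49872 to 49944, plus strand) rose from 6.77 ± 0.135 to 15.1 ± 2.40 CPM (SD, n = 2 each, log2 fold change 1.16, SE 0.18, adjusted p = 0.0015). The nearby ndhJ, for a subunit of the plastid NADH dehydrogenase-like complex, rose by 1.52 (SE 0.28, adjusted p = 0.003). For ndhK (ZemaCp028, 51118 to 51801, minus strand), of the same complex, a single library decided the call. Its fragments were 247 and 269 in control and 1782 and 224 in cold, for a log2 fold change of 2.26 (SE 0.70, adjusted p = 0.027) that became 0.37 (adjusted p = 0.15) without cold replicate 1 and 3.06 without cold replicate 2. It was not called with DESeq2 (adjusted p = 0.10) or without control replicate 2 (adjusted p = 0.053). The 3 tested ribosomal RNA loci were higher, by 1.58 (ZemaCr119, adjusted p = 0.00063), 1.78 (ZemaCr114, adjusted p = 0.026) and 2.25 (ZemaCr120, adjusted p = 0.035). The calls of ZemaCr114 and ZemaCr120 were lost with a library left out, at adjusted p = 0.12 and 0.14 without control replicate 2, and at 0.095 and 0.22 without cold replicate 2. The log2 fold change of ZemaCr120 was 1.27 without cold replicate 2, 2.87 without cold replicate 1 and 3.23 without control replicate 1. Plastid ribosomal RNA genes lie in inverted repeats, so reads that map to both copies were not counted. The photosystem I gene psaA rose by 1.44 (SE 0.35, adjusted p = 0.010; 0.066 without control replicate 2). For rbcL, the large subunit of Rubisco, the change was 0.27 (SE 0.16, adjusted p = 0.20; 0.043 without cold replicate 2).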

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

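The alternatives for mitochondrial and plastid genes taken apart, short RNA loci, neighbouring genes, and genes named outside the rule (by position, or organelle genes other than ndhK, rrn18, trnF and rrn26) were chosen after seeing the data; the rest were planned. In each alternative run, 0 of the genes called in the main test were called in the opposite direction. Under RLE factors 6493 genes were higher and 5973 lower, without the 20 most abundant genes 6250 and 6257, with DESeq2 5778 and 5018, with no low-count filter 6701 and 6761, and with the stricter filter 5116 and 4953. A requirement of a 2-fold change left 3487 higher and 3395 lower genes, and an adjusted p under 0.01 left 4451 and 3956, which follows from the stricter rules. Leaving out 1 library gave between 4599 and 6395 higher and between 4117 and 6452 lower genes. The low counts came without a control library, and the cause was not tested. The spread is then estimated from the cold pair alone, which differed more between its libraries (chi-square per degree of freedom 25 against 11.3 in control). The labels do not say that the replicate numbers pair the libraries. Deviations of same-numbered libraries from their condition means correlated at -0.0711, which with 2 libraries per condition is 1 independent value and does not settle it. With the replicate number as a block 5829 genes were higher and 5808 lower, and rps2B (adjusted p = 0.077), ZemaCr114 (0.054) and ZemaCr120 (0.056) were not called. The organelle list had a median log2 fold change of 0.26 (p = 0.164) under the stricter filter, which removes most of its genes, 0.83 (p = 0.135) with an estimated correlation, 0.77 (p = 0.0127) with the replicate block, and between 0.74 and 0.90 with a library left out. Under the other scalings, no filter and fry it lay between 0.63 and 0.86 and stayed past the threshold. In the run without a filter, the organelle, mitochondrial, plastid and short RNA sets still held only genes that passed the main filter. That run therefore cannot tell how the removed organelle genes moved. The mitochondrial list lost its call under the stricter filter (camera with a preset correlation, p = 0.135) and with an estimated correlation (p = 0.0688). Its median was between 0.98 and 1.24 in all alternatives, with 10 to 17 genes higher (3 under the stricter filter) and 0 lower. The 4 nuclear genes named by identifier and the 4 named for their shift in CPM were called in the same direction in every alternative that tested them. Counts of up to 10 fragments in a control library limit ccmFC, ccmFN, atp6, ZemaCr114 and ZemaCr120, and camera was not run on a DESeq2 fit. Alternatives planned for normalized values were not run because the table holds counts.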

Other observations

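The tests of carry-over, genomic DNA, scaling and misassigned reads, the regions, and the splits by abundance and exon number were chosen after the result was seen; the test of abundance, length and exon number in neighbouring genes was set before its result.

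Runs of neighbouring genes called in one direction were more frequent than in permutations within chromosomes. The regions named here were picked after their values were seen, and no single region was tested. On chromosome 8, 6 consecutive tested genes between 173415190 and 173587177 (B73 RefGen_v4) rose with a median log2 fold change of 3.39 and up to 7.14, and their summed level went from 94.3 to 986 CPM. All 6 were called with each scaling and with each library left out. On chromosome 2, 6 genes between 221760272 and 221920555 rose by a median of 1.67, and 6 genes between 42049274 and 42356555 fell, with a median of -1.36 and a summed level of 233 CPM in control and 105 CPM in cold. Both runs also held with each scaling and each library left out. Each other run of at least 6 genes lost calls in some alternative. The longest run had 11 genes on chromosome 1 (43080647 to 43446781), higher by a median of 1.26, of which 7 were called without control replicate 1; a share of 0.025 of 1000 permutations had a run at least as long, the longest with 14 genes. There were 31 runs of at least 6 genes, against a mean of 13.1 and a highest value of 24 in 1000 permutations within chromosomes (p = 0.001, the smallest they can give). Without control replicates 1 and 2 there were 6 and 7 runs, with DESeq2 14, with an adjusted p under 0.01 there were 5, and with a required 2-fold change there was 1.

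Increases were called more frequently among abundant genes. A change of a given size is easier to call in a gene with more fragments, and this was not separated from the response. With TMM factors the median log2 fold change was -0.22 in the lowest and 0.17 in the highest of the bins described next. With nuclear genes ranked by mean level into 5 equal bins, 40% of the highest bin were higher and 18.4% lower in cold, while in the lowest bin 16.7% were higher and 22.9% lower. The share of higher genes stayed larger in the highest bin in all the scalings, DESeq2 and with each library left out, for example 30.5% against 14.3% with library totals alone and 39.4% against 12.2% with DESeq2. The share of lower genes did not keep its order. It was 29.5% in the highest and 28.4% in the lowest bin with library totals alone, 16.8% and 13.6% with DESeq2, 20.7% and 19.9% without cold replicate 1, and 21.5% and 18.2% without cold replicate 2. In both directions, large changes were more frequent in single-exon genes than in genes with over 10 exons. They were also more frequent in the lowest than in the highest abundance bin. Decreases of at least 4-fold were found for 8.63% of single-exon genes and 0.968% of genes with over 10 exons, and for 11.5% of the lowest and 0.935% of the highest abundance bin. Increases of that size were found for 8.04% and 2.77% by exon number, and for 9.4% and 5.7% by abundance. The order was not steady between these ends for increases. Genes with 2 exons had 8.13%, and the middle abundance bins had between 3.44% and 5.48%. These differences were not tested, and exon number was not separated from abundance. Fold changes of genes with few fragments are also less exact, and only large ones can be called there. The higher share of large changes in the lowest bin may therefore reflect counting noise. As sets, single-exon genes (960 higher and 1074 lower of 3883) and genes with over 10 exons (840 and 678 of 2995) were not called against the other genes (camera adjusted p = 0.63 and 0.631), nor were the 169 genes on unplaced contigs (50 and 42, adjusted p = 0.63).

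Mitochondrial transcripts were higher in cold by a median of 1.18 on the log2 scale. More RNA without poly(A) tails in the cold libraries might raise both organelles alike, which was not shown. The mitochondrial median exceeded the plastid median by 0.81 (permutation of genes, p = 0.00147). The gene sets differ in class and level, so this difference cannot decide whether such carry-over played a part. All 3 tested ribosomal RNA genes of each organelle were higher, with a median log2 fold change of 1.18 in the mitochondrion and 1.78 in the plastid. The mitochondrial genes compared include rbcL-ct and the other genes named with -ct. Genomic DNA would add the same number of fragments per kb to each mitochondrial gene if all its reads were counted. The rise among called genes ran from 0.392 to 156 CPM per kb. Rises in disjoint library pairs ranked the 27 genes alike (rank correlation 0.64, one-sided permutation p = 0.00019). Reads that mapped to several places were left out, however. Added DNA could therefore also raise genes unequally and rank them alike in both pairs, so the ranking cannot decide. The 7409 nuclear genes with a mean under 0.5 CPM held a cold to control ratio of 1.01 (upper 95% bound 1.04). That ratio covers nuclear DNA only, and the amount of mitochondrial DNA was not measured. With library totals alone the mitochondrial median was 0.98 while that of all genes was -0.241 (camera with a preset correlation, p = 0.000371). Another scaling moves all genes by about the same amount, so comparing the list with other genes could not decide whether scaling played a part. Under these totals 12 mitochondrial genes were called higher and 0 lower. In camera with TMM factors and an estimated correlation the call of the list was lost (p = 0.0688, adjusted p = 0.473). A higher mitochondrial transcript level after a day of cold remains a hypothesis. Carry-over and genomic DNA were not decided by the values above. Unequal mapping, longer poly(A) tails on mitochondrial RNA and a change in the mix of tissues are open, untested alternatives.

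Adjacent genes that start close together on opposite strands tended to change together: the rank correlation was 0.278 over 275 such divergent pairs within 1 kb. Of the 86 pairs with both genes called, 77.9% had a common direction, against 55% of 6737 such pairs over all neighbours. For divergent pairs the share was 68.1% with a gap of 1 to 3 kb and 47.6% with a gap of 3 to 10 kb. It was 76.9% in overlapping divergent pairs and 88.9% in overlapping same-strand pairs. Reads counted for the wrong gene would bind convergent pairs, whose transcript ends meet, at least as strongly, but their correlation was 0.066 and the difference of 0.212 had a permutation p of 0.002. Genes sharing traits such as length may respond alike, but after abundance, length and exon number were removed by a linear fit the correlation was 0.268 (p = 0.001, the smallest that 1000 permutations can give), so most of it does not come from these traits. Same-strand pairs within 1 kb also changed together (0.171 over 621 pairs), which a shared promoter between divergent genes would not cover. For divergent pairs a shared promoter region that responds to cold as a unit is a candidate explanation and would be testable against the nucleosome maps named in the series, while gene models that split a transcript and duplicated neighbours were not tested.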
